A study of Mus musculus with 14 samples.

How the data were processed

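RNA was measured in 14 libraries from tumours of LLC1 cells, the mouse Lewis lung carcinoma line, grown in mice. Per the labels' protocols the RNA came from a fraction enriched for tumour cells and the libraries from a stranded total RNA kit, while the series' design text describes the material as a bulk suspension of single tumour cells. The labels give 4 groups, namely vehicle (DMSO, 4 libraries), MYCi975 (4 libraries), TMP195 (3 libraries) and the combination of both compounds (3 libraries). Each single agent was given at 50 mg/kg and treatment lasted 16 days. The doses within the combination are not given in the sources used here. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical in part.

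The deposited values are log2-scale expression values after a variance-stabilising transformation, made by the authors and deposited as 1 table of 21152 genes by 14 libraries, per the file headers and the file's name. The submitters' processing notes name Salmon, with no version, and the genome build hg38. That build is human, whereas the identifiers in the table are mouse Ensembl gene IDs, so the build behind the values is not settled here and no coordinates are printed. Any filter or library scaling before the transformation is not given in the sources used here. All libraries share 1 lowest value, 4.047, which stands for no reads. Values above it do not lie on steps, so read counts could not be recovered, the depth of the libraries is unknown, and no count model was used. Differences on this scale understate the fold of genes near the floor. Of the 21152 IDs, 20264 (95.8%) matched a mouse gene symbol and 888 did not.

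The following choices were made before the data were examined. Genes were tested when their mean over all libraries lay more than 1 log2 unit above the floor, which left 13711. A linear model with 1 mean per group was fitted to all 14 libraries with limma 3.58.1 in R 4.3.3, so that all groups shared 1 estimate of the spread (10 residual degrees of freedom), with empirical Bayes moderation along an intensity trend (prior degrees of freedom 5.275). There were 6 comparisons: each treatment against vehicle, the combination against each single agent, and the interaction of MYCi975 and TMP195, which is the difference between combination and TMP195 minus the difference between MYCi975 and vehicle. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. There were 44 gene lists fixed from textbook knowledge, 29 of pathways and 15 of cell type markers, of which 42 had at least 3 tested members. The lists of keratinocyte and adipocyte markers had 1 and 2 tested members and were not tested. Lists were tested with limma's camera, which compares a list with all other tested genes, at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The fry rotation test, which asks whether a list's genes move on balance 1 way without comparing them with other genes, was run beside it. The list mean of a library is the mean of its members' values after each gene was centred on its mean over the 14 libraries, and the 95% interval of a difference in list means comes from the spread of these means over libraries. These intervals were not adjusted for the number of lists or comparisons, so some can exclude 0 by chance.

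Genes were named by a rule. For the comparisons with vehicle it took the genes past the threshold with the greatest change (there were none), up to 2 members with the smallest p of each list discussed, and always Myc, Hdac4, Hdac5, Hdac7, Hdac9, Hif1a and Ppargc1a. For the other comparisons it took, where nothing passed, the 3 smallest p in each direction, leaving out predicted genes, clone names and pseudogenes. The genes with the 3 smallest p in each direction against vehicle were added after the values were seen. So were Ptprc, mt-Rnr2, Xist, the Y-linked genes, the genes of the first principal component and the further members of lists that passed when adjusted over the list alone. Genes of families with near-identical copies, among them ribosomal protein, histone, haemoglobin, guanylate-binding protein and major histocompatibility genes, are uncertain as single genes, since reads shared between copies can be split in the authors' quantification.

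Alternatives set beforehand were no filter on low values, a filter 2 log2 units above the floor, moderation without a trend, robust moderation, median centring, quantile normalisation, library weights, only the libraries of the groups compared, the replicate number as a term, leaving out each library in turn, and the estimated correlation. Added after seeing the data were an exact permutation test of list means over libraries, the count of lists called by fry, and the values of Ptprc, mt-Rnr2 or the Y-linked genes as a covariate. No library was left out of the main comparisons. The 14 libraries were checked for duplicates: the highest correlation between 2 libraries was 0.981, and that pair shared 0 identical values above the floor.

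The gene and list tests were tested on simulated normal values with the means and moderated spreads of the 13711 genes, with 200 genes changed. For MYCi975 against vehicle 86.7% of the genes changed by 1 log2 unit and 18.2% of those changed by 0.5 were called. For TMP195 against vehicle the shares were 75.0% and 15.3%, and for the combination against vehicle 80.0% and 10.0%. All genes changed by 2 log2 units were called (100%) in these 3 simulated comparisons. Simulated genes were independent of each other, unlike genes in tissue. In the real data the median gene's 95% interval reached 0.37 log2 units to either side for MYCi975 against vehicle, 0.39 for TMP195 or the combination against vehicle, and 0.56 for the interaction.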

Results

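Tumours of LLC1, the mouse Lewis lung carcinoma line, were profiled by RNA sequencing after 16 days of treatment of the host mice. The treatments were vehicle (n = 4 libraries), MYCi975 (n = 4), TMP195 (n = 3) or both compounds (n = 3). MYCi975 is a small-molecule inhibitor of the transcription factor MYC, and TMP195 inhibits the class IIa histone deacetylases HDAC4, HDAC5, HDAC7 and HDAC9. The series asks which transcriptional changes the drugs induce in vivo, and its title points to mitochondrial dysfunction. Values are normalised expression on a log2 scale with a floor of 4.047. The depth of the libraries is unknown, and the number of genes at the floor ran from 880 in vehicle replicate 1 to 2954 in MYCi975 replicate 2.

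The first principal component held 28.7% of the variance between the libraries and followed Ptprc, which encodes the pan-leukocyte antigen CD45. Vehicle, MYCi975 and TMP195 libraries each lay on both sides of it, while the 3 combination libraries lay on one side (8.70, 13.6 and 26.1), with a difference from vehicle of 14.9 (exact permutation p = 0.0857). At one end lay MYCi975 replicate 2 with a score of -52.7, followed by TMP195 replicate 3 at -21.9, and at the other end combination replicate 1 at 26.1. The largest loadings belonged to Ttn, a muscle gene, at the first end (-0.0466) and to the histone gene Hist1h2aj at the other (0.045). Which kinds of genes the component favours was not tested. Genes at the first end also included Acod1, Nlrp3, Il1b and Cxcl2 of activated myeloid cells and the interferon-induced genes Gbp5, Mx1 and Cxcl9. Il1b was 12.92 in MYCi975 replicate 2 against 9.94 to 11.52 in the other libraries, and Acod1 was 11.17 against 7.55 to 9.66. Genes at the other end also included the stromal genes Lum, Aspn and Mmp3 and the haemoglobin genes Hba-a1 and Hbb-bs. Ptprc was 12.07 in MYCi975 replicate 2 and 9.65 in combination replicate 1. Over the other 13 libraries, with the component computed without MYCi975 replicate 2, it followed Ptprc with Pearson's r = -0.93 (permutation p = 7e-05, adjusted p = 0.000233) and Spearman's rho = -0.90 (permutation p = 0.00013, adjusted p = 0.000433). Without the 2 libraries farthest from the median of Ptprc r was -0.77. This relation was 1 of 10 computed, of which 2 are not given because the values of the Y-linked genes in them fall in separate clusters. Mean Ptprc was 10.60 ± 0.30 (SD, n = 4) with vehicle, 10.85 ± 0.88 (n = 4) with MYCi975, 10.84 ± 0.53 (n = 3) with TMP195 and 10.04 ± 0.36 (n = 3) with the combination. The combination and vehicle differed in Ptprc by -0.56 (exact permutation p = 0.0857, two-sided, where 0.0286 is the smallest p that 4 against 3 libraries allow).

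**Figure D1:**
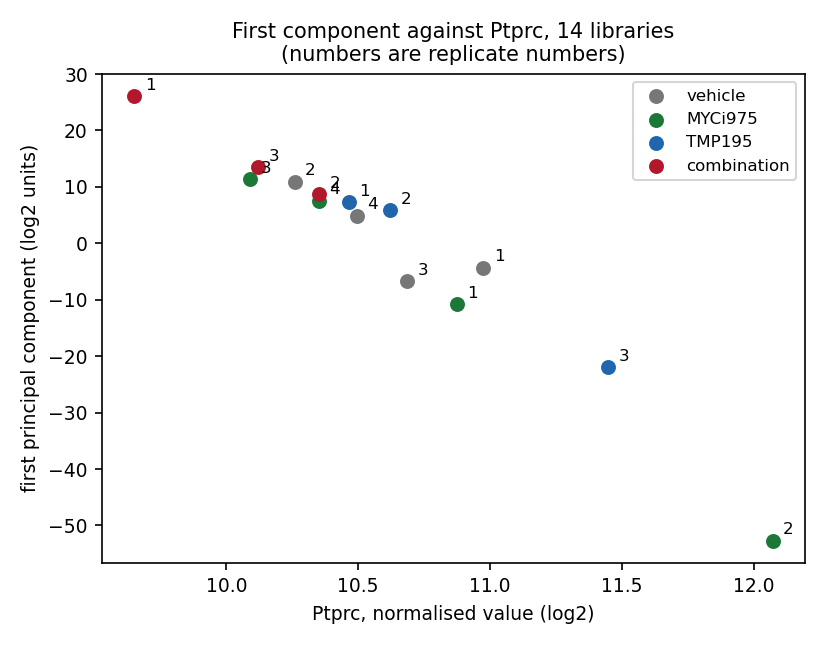
First principal component of the 13711 tested genes (vertical axis, log2 units) against the normalised value of Ptprc (horizontal axis, log2) in the 14 libraries, coloured by treatment and numbered by replicate. MYCi975 replicate 2 lies alone at a Ptprc of 12.07 and a component score of -52.7, and the 3 combination libraries lie between 9.65 and 10.35 on the Ptprc axis.

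The transcripts of the drug targets were measured in all groups, and none passed the test against vehicle over all genes. Myc (ENSMUSG00000022346.18) averaged 8.97 ± 0.25 (SD, n = 4) with vehicle, 9.13 ± 0.26 (n = 4) with MYCi975, 9.04 ± 0.10 (n = 3) with TMP195 and 9.07 ± 0.07 (n = 3) with the combination. Its log2 difference from vehicle was 0.16 with MYCi975 (95% interval -0.15 to 0.47). Hdac5 (ENSMUSG00000008855.18) averaged 7.90 ± 0.13 with vehicle, 8.22 ± 0.03 with MYCi975, 8.36 ± 0.30 with TMP195 and 8.04 ± 0.13 with the combination. Hdac4 averaged 8.31 ± 0.32 with vehicle and 8.73 ± 0.32 with TMP195. Hdac7 averaged 7.87 ± 0.10 with vehicle and 7.98 ± 0.10 with TMP195, and Hdac9 averaged 5.60 ± 0.34 and 5.67 ± 0.12. Hif1a, the oxygen-regulated subunit of hypoxia-inducible factor, averaged 11.52 ± 0.18 with vehicle, 11.75 ± 0.28 with MYCi975, 11.72 ± 0.08 with TMP195 and 11.38 ± 0.52 with the combination. Ppargc1a, a coactivator of mitochondrial biogenesis, lay between the floor and 4.85 in all libraries and was not tested. None of these genes passed limma's test in any comparison with vehicle after adjustment over all genes. The compounds inhibit proteins, whose activity was not measured, so these RNA values do not show whether the targets were inhibited.

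**Figure D2:**
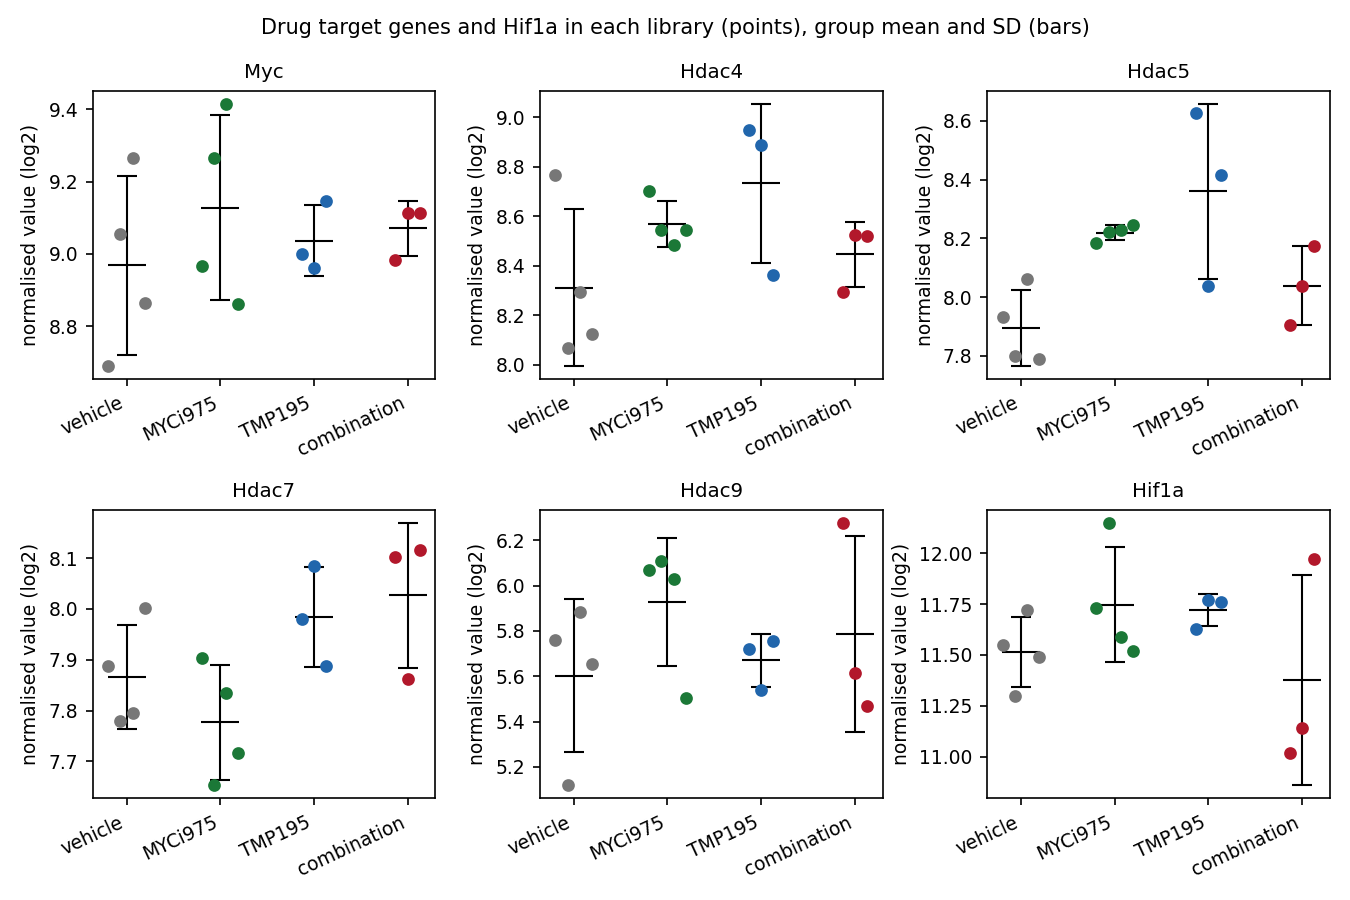
Normalised values (log2) of Myc, Hdac4, Hdac5, Hdac7, Hdac9 and Hif1a in each library (points) for vehicle (4), MYCi975 (4), TMP195 (3) and the combination (3), with group mean and SD (bars). Group means of Myc lie between 8.97 and 9.13, and those of Hdac5 between 7.90 and 8.36.

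With MYCi975, genes of the immediate early and dissociation response and neutrophil markers ranked above other genes relative to vehicle, and cytosolic ribosomal protein genes ranked below them. These calls by camera were lost with an estimated correlation (adjusted p = 0.80 for each). Of 21 immediate early and dissociation genes 20 were higher, with a mean log2 difference of 0.43. Examples were Atf3, a stress-induced transcription factor (0.72), and the heat shock gene Hspa1b (0.69). All 10 neutrophil markers were higher, by 0.56 on average, among them S100a9 (0.75) and Lcn2 (0.55). Of 13 genes responsive to MEF2, the transcription factors that class IIa deacetylases repress, 12 were higher, with a mean of 0.33, led by Egr1 (0.80) and Nr4a1 (0.58). Egr1, Nr4a1 and Jun also belong to the immediate early list, so these lists are not independent. Of the 7 genes of class IIa deacetylases and MEF2 factors 6 were higher, by 0.25 on average, including Hdac5 (0.32) and Mef2d (0.46). Of 9 genes of the MYC network 8 were higher (mean 0.23), among them Max (0.28) and Mlx (0.41). Of 79 cytosolic ribosomal protein genes 69 were lower, by -0.16 on average, for example Rpl7a (-0.33) and Rplp0 (-0.28). Cholesterol synthesis genes averaged -0.12, with Mvk, an enzyme of the pathway, at -0.43.

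For the mitochondrial genes that the series' title points to, respiratory complexes II to V averaged -0.07 with MYCi975 (26 of 39 genes lower, Sdhc -0.27, Cyc1 -0.31). Complex I averaged -0.04, with Ndufb2 at 0.32 and Ndufs7 at -0.22. Mitochondrial ribosomal protein genes averaged -0.05, including Mrps16 (-0.49) and Mrpl57 (-0.46), and tricarboxylic acid cycle genes -0.05, with Sdhc at -0.27 and Dld at 0.17. The 60 MYC-responsive genes averaged -0.0048, with members on both sides such as Wdr74 (-0.46) and Fbl (0.57). Cell cycle genes averaged -0.08, with Bub1 at -0.34 and Ccnb2 at -0.31. Hypoxia response and glycolysis genes each averaged 0.09 and were not called, and glycolysis averaged -0.015 without MYCi975 replicate 2. The list encoded in the mitochondrial genome averaged -0.03, with -0.24 without vehicle replicate 3 and 0.32 without vehicle replicate 4, and was called in 0 of 14 fits that left out 1 library. In these fits complex I ran from -0.10 (without vehicle replicate 1) to -0.015 (vehicle replicate 3), the mitochondrial ribosome from -0.09 (vehicle replicate 1) to -0.017 (MYCi975 replicate 2) and the tricarboxylic acid cycle from -0.09 (vehicle replicate 1) to -0.0067 (vehicle replicate 3). MYC-responsive genes ran from -0.05 (without MYCi975 replicate 3) to 0.03 (MYCi975 replicate 1). Interferon response genes averaged 0.18 with all libraries, -0.13 without MYCi975 replicate 2 and -0.0096 with Ptprc as a covariate. By camera, 10 of 42 lists were called for MYCi975 against vehicle, 6 higher and 4 lower, with adjusted p = 5.3e-07 for the immediate early list, 6.8e-06 for neutrophil markers, 1.1e-05 for cytosolic ribosome and 0.026 for complexes II to V, interferon response and cell cycle. None held with an estimated correlation, where the adjusted p of these 10 lists ran from 0.80 to 0.85. The immediate early list mean differed by 0.43 with a 95% interval over libraries of -0.14 to 0.99. Without MYCi975 replicate 2 this difference was 0.22, that of neutrophil markers 0.21, of MEF2-responsive genes 0.13, of the MYC network 0.11, of class IIa deacetylases and MEF2 factors 0.16, of cytosolic ribosome -0.015 and of cell cycle -0.0097. Without it the calls ended for all 10 lists but the immediate early list and cholesterol synthesis (-0.18). In that fit 7 lists were called, 2 of them among the 10. The call of cholesterol synthesis ended without vehicle replicate 1 (-0.07) or MYCi975 replicate 1 (-0.06) or 3 (-0.09), and that of cytosolic ribosome also without vehicle replicate 2 (-0.03). The call of complexes II to V also ended without vehicle replicate 2 (-0.07), 3 (-0.04) or 4 (-0.04) or MYCi975 replicate 1 (-0.05), and their mean was -0.14 without vehicle replicate 1. The call of class IIa deacetylases and MEF2 factors also ended without vehicle replicate 2 (0.19) or MYCi975 replicate 1 (0.23), that of interferon response without vehicle replicate 2 (0.10) or 4 (0.12) or MYCi975 replicate 1 (0.17), and that of cell cycle without vehicle replicate 3 (-0.02) or MYCi975 replicate 1 (-0.08) or 4 (-0.06). Other means moved by over 1.5 times: cytosolic ribosome to -0.30 without MYCi975 replicate 4, interferon response to 0.42 without MYCi975 replicate 3 and 0.30 without vehicle replicate 3, and cell cycle to -0.16 without MYCi975 replicate 3.

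No single gene passed limma's test for MYCi975 against vehicle (0 of 13711, smallest adjusted p = 0.999). At an unadjusted p under 0.05 there were 457 genes, 253 higher and 204 lower, where 5% of the tested genes is 686. The genes with the smallest p were Ctr9, a subunit of the PAF1 elongation complex (0.51), Dtnb (0.51) and Gadd45a, a stress-induced gene (0.64) on the higher side, and Taf6l (-0.63), Eml2 (-0.93) and Paqr7 (-0.58) on the lower side. They were chosen after the values were seen.

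With TMP195, hypoxia response and glycolysis genes ranked above other genes relative to vehicle, and cell cycle and MYC-responsive genes ranked below. With an estimated correlation these calls by camera were lost (adjusted p = 0.64 for hypoxia response and MYC-responsive genes and 0.71 for glycolysis and cell cycle). Of 23 hypoxia response genes 18 were higher, by 0.20 on average (95% interval over libraries 0.01 to 0.39), including Ndrg1 (0.57) and Mxi1, a MYC antagonist (0.47). Of 21 glycolysis genes 18 were higher, by 0.18 on average, among them the glucose transporter gene Slc2a1 (0.27) and Pfkfb3 (0.55). Slc2a1, Ldha and Pgk1 belong to both the hypoxia response and the glycolysis list, so these lists are not independent. Of 46 cell cycle genes 40 were lower, by -0.16 on average, such as Gins2 (-0.54) and Ccna2 (-0.36). For glycolysis and cell cycle the 95% interval over libraries spanned both signs. Of 60 MYC-responsive genes 47 were lower, with a mean of -0.12 (95% interval -0.25 to 0.01), such as Cbx3 (-0.36) and Tfb2m, a mitochondrial transcription factor (-0.52). Among class IIa deacetylases and MEF2 factors 6 of 7 were higher, by 0.17 on average, led by Hdac5 (0.47) and Hdac4 (0.42). MEF2-responsive genes, in contrast, averaged 0.04 and were not called, with means from -0.09 without TMP195 replicate 3 to 0.15 without TMP195 replicate 2. Their members lay on both sides, with Adamts1 at 0.76 and the muscle gene Des at -0.67. Skeletal muscle markers were lower in this comparison (-1.27), and how far muscle RNA moved the mean of MEF2-responsive genes was not tested. Antioxidant response genes averaged 0.17, led by Gclm, the modifier subunit of the enzyme that starts glutathione synthesis (0.99), and endoplasmic reticulum stress genes averaged 0.09, with Sel1l at 0.24 and Hyou1 at 0.25.

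Lists of nuclear genes for mitochondrial proteins averaged slightly lower with TMP195, and those called by camera were lost with an estimated correlation (adjusted p = 0.74 for complex I, 0.79 for complexes II to V and 0.73 for the mitochondrial ribosome). Complex I averaged -0.07 (30 of 36 genes lower, Ndufa9 -0.27), complexes II to V -0.09 (25 of 39 lower, Sdhc -0.42, Atp5l -0.44) and the mitochondrial ribosome -0.08 (54 of 78 lower, Mrps6 -0.41, Mrps26 -0.44). The tricarboxylic acid cycle list averaged -0.08 and was not called, with Suclg2 at -0.46, and ran from -0.12 without TMP195 replicate 3 to -0.03 without vehicle replicate 3. The list encoded in the mitochondrial genome averaged -0.13 and was not called, with 0.42 without TMP195 replicate 1 and -0.51 without TMP195 replicate 3. Without TMP195 replicate 1 complexes II to V averaged -0.0076 and complex I -0.02, and without vehicle replicate 1 they averaged -0.16 and -0.13. Neutrophil markers averaged 0.35 and antigen presentation genes 0.22, and the latter averaged -0.05 without TMP195 replicate 3. The 6 skeletal muscle markers averaged -1.27, with Myh4 at -1.84. Vehicle replicates 3 and 2 carried the most muscle RNA of the vehicle libraries, with list means of 2.12 and 0.79 against -1.08 in vehicle replicate 4, and without vehicle replicate 3 the difference was -0.73. By camera, 13 of 42 lists were called for TMP195 against vehicle, 7 higher and 6 lower, with adjusted p = 1.1e-06 for cell cycle, 1.1e-05 for hypoxia response, 1.2e-05 for MYC-responsive genes, 0.00034 for glycolysis and for skeletal muscle markers, 0.0012 for the mitochondrial ribosome, 0.014 for complexes II to V and 0.042 for complex I. None held with an estimated correlation, where the adjusted p of these 13 lists ran from 0.64 to 0.87. The calls of glycolysis, hypoxia response, MYC-responsive genes, cell cycle and skeletal muscle markers held in all 14 fits that left out 1 library. MYCi975 and combination libraries enter this comparison only through the shared spread and the filter on low values, so leaving them out is a weaker check. With the replicate number as a term, the calls of complex I (-0.05), complexes II to V (-0.06), endoplasmic reticulum stress genes (0.08), antioxidant response (0.15), class IIa deacetylases and MEF2 factors (0.15) and antigen presentation (0.16) ended. Calls also ended without at least 1 library: complex I without vehicle replicate 2 (-0.06), 3 (-0.04) or 4 (-0.05) or TMP195 replicate 1, complexes II to V without vehicle replicate 3 (-0.06) or 4 (-0.05) or TMP195 replicate 1, and the mitochondrial ribosome without vehicle replicate 3 (-0.06) or TMP195 replicate 1 (-0.05). Neutrophil markers lost it without vehicle replicate 3 (0.24) or TMP195 replicate 1 (0.26) or 2 (0.25), antigen presentation without vehicle replicate 2 (0.11) or 4 (0.16) or TMP195 replicate 3, and class IIa deacetylases and MEF2 factors without vehicle replicate 2 (0.11) or TMP195 replicate 1 (0.17) or 3 (0.14). Antioxidant response lost it without vehicle replicate 1 (0.16), 2 (0.13) or 4 (0.14) or TMP195 replicate 3 (0.13), and endoplasmic reticulum stress genes without vehicle replicate 1 (0.05), MYCi975 replicate 2 (0.09) or TMP195 replicate 2 (0.09) or 3 (0.07). Without TMP195 replicate 3 the means were -0.12 for complex I, -0.14 for complexes II to V and 0.54 for neutrophil markers, without TMP195 replicate 1 0.42 for antigen presentation, without vehicle replicate 1 -0.13 for the mitochondrial ribosome and without vehicle replicate 3 -0.10 for cell cycle.

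No gene passed limma's test for TMP195 against vehicle over all genes (0 of 13711), and 381 had an unadjusted p under 0.05, 202 higher and 179 lower. Adjusted over the list alone, Hdac5 (adjusted p = 0.032, 7 genes) and Gclm (adjusted p = 0.030, 19 genes) passed limma's test, in 2 of 42 lists examined, against 0 of 42 lists for MYCi975 or the combination against vehicle. No adjustment was made over the 42 lists, so a few lists with a passing member can arise by chance. Hdac5 no longer passed without TMP195 replicate 1 or vehicle replicate 2 or 4, where 0 genes of its list passed, and 2 did without vehicle replicate 1. For Gclm's list the count was 0 without TMP195 replicate 2 or vehicle replicate 1, 2 or 4, and 2 without TMP195 replicate 1. Among the genes with the smallest p were Bmp4, a secreted growth factor of the TGF-beta family (1.17), Snrk (0.65) and Gclm on the higher side, and Prss23 (-0.82) and Sdhc, a subunit of succinate dehydrogenase (-0.42), on the lower side.

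With the combination, interferon response and antigen presentation genes and markers of T cells and of cytotoxic and NK cells ranked below other genes relative to vehicle. Camera called these lists at its preset correlation but not with an estimated correlation (adjusted p = 0.78 for each). All 29 interferon response genes were lower, by -0.52 on average (95% interval over libraries -1.34 to 0.30), for example Cxcl9 (-1.11) and Gbp3 (-0.91). Of 20 antigen presentation genes 19 were lower, by -0.55 on average, including the class II chaperone genes H2-DMa (-0.64) and H2-DMb1 (-0.81). All 17 T cell markers were lower (mean -0.34), such as the T cell receptor kinases Lck (-0.63) and Zap70 (-0.39), and all 8 cytotoxic and NK cell markers (mean -0.56), such as Klrk1 (-0.94) and Ifng (-0.79). Inflammatory cytokines averaged -0.30 (Ccl2 -0.57, Ccl12 -0.44), macrophage markers -0.27 (Ms4a7 -0.83, but Mertk 0.29), neutrophil markers -0.31 (Trem1 -0.57) and endothelial markers -0.20 (Erg -0.46, Egfl7 -0.37). B cell and dendritic cell markers averaged -0.08 and -0.07 and were not called. Ptprc differed by -0.56 in the same comparison. With it as a covariate 14 lists were called, 5 of them among the 12 of the main fit. Interferon response then averaged -0.08, antigen presentation -0.15, T cell markers -0.08 and macrophage markers -0.0010. Ptprc is itself a leukocyte gene measured after treatment, so this covariate would also remove a real change in leukocytes. Without combination replicate 1 the interferon response list averaged -0.34, the antigen presentation list -0.29 and inflammatory cytokines -0.19, and without combination replicate 3 macrophage markers averaged -0.16 and endothelial markers -0.13.

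Respiratory chain genes ranked slightly below other genes with the combination relative to vehicle, and these calls too were lost with an estimated correlation (adjusted p = 0.78 for each). Complex I averaged -0.11 (29 of 36 genes lower, Ndufs4 -0.34, Ndufb10 -0.31) and complexes II to V -0.12 (30 of 39 lower, Atp5l -0.63, Uqcrc1 -0.26), with 95% intervals over libraries of -0.25 to 0.04 and -0.33 to 0.09. All 13 genes encoded in the mitochondrial genome were lower, by -0.46 on average, with a wide interval of -1.79 to 0.87 (mt-Nd3 -0.61, mt-Nd4l -0.58). Over the 14 libraries this list followed the number of genes at the floor (r = 0.65, rho = 0.63, permutation p = 0.0138 and 0.018, adjusted p = 0.0276 and 0.036; r = 0.61 without the 2 libraries farthest from the median), which was also lower in the combination than in vehicle libraries (-180.6, exact permutation p = 0.771). The mitochondrial ribosome (-0.05, Mrpl35 -0.42), the tricarboxylic acid cycle (-0.06), MYC-responsive genes (-0.02), hypoxia response (-0.04, Car9 0.45), glycolysis (-0.09), cell cycle (-0.01), class IIa deacetylases and MEF2 factors (0.03) and MEF2-responsive genes (0.09, Adamts1 0.86) were not called. Leaving out 1 library turned the sign of hypoxia response (0.04 without combination replicate 1), cell cycle (0.05 without vehicle replicate 3) and class IIa deacetylases and MEF2 factors (-0.03 without vehicle replicate 2). Glycolysis ran from -0.18 (without combination replicate 3) to -0.011 (combination replicate 1), the mitochondrial ribosome from -0.10 (vehicle replicate 1) to -0.02 (vehicle replicate 3) and the tricarboxylic acid cycle from -0.10 to -0.02 without the same libraries. MYC-responsive genes ran from -0.06 (without combination replicate 3) to -0.00047 (combination replicate 1) and MEF2-responsive genes from 0.0053 (vehicle replicate 2) to 0.17 (vehicle replicate 3). Without combination replicate 3 the mean of the mitochondrially encoded list was -0.09. Without vehicle replicate 1 complex I averaged -0.16 and complexes II to V -0.19, and without combination replicate 1 complex I averaged -0.06. Skeletal muscle markers averaged -0.87, and -0.32 without vehicle replicate 3.

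By camera, 12 of 42 lists were called for the combination against vehicle, all lower, with adjusted p = 3.8e-10 for interferon response and for antigen presentation, 9.3e-06 for T cell markers, 4.4e-05 for cytotoxic and NK cell markers, 0.0049 for complexes II to V, 0.0079 for complex I and 0.010 for the mitochondrially encoded list. None held with an estimated correlation, where the adjusted p of each was 0.78. The calls of interferon response, antigen presentation, inflammatory cytokines, T cell and cytotoxic and NK cell markers held in all 14 fits that left out 1 library. Fits without a MYCi975 or TMP195 library are again a weaker check, since these libraries lie outside the comparison. Complex I lost its call without vehicle replicate 3 (-0.08) or 4 (-0.09) or combination replicate 1 or 3 (-0.10), and complexes II to V without vehicle replicate 3 (-0.09) or 4 (-0.08) or combination replicate 1 (-0.08) or 3 (-0.09). The mitochondrially encoded list lost it without vehicle replicate 2 (-0.41) or 4 (-0.11) or combination replicate 3. Neutrophil markers lost it without vehicle replicate 1 (-0.24), 2 (-0.27) or 4 (-0.30) or combination replicate 1 (-0.21) or 2 (-0.34), endothelial markers without vehicle replicate 2 (-0.13) or combination replicate 3, macrophage markers without vehicle replicate 3 (-0.17) or combination replicate 3, and skeletal muscle markers without vehicle replicate 2 (-0.76) or 3 or combination replicate 3 (-0.44). The mean of the mitochondrially encoded list was -0.83 without combination replicate 1, that of complexes II to V -0.18 without combination replicate 2 and that of skeletal muscle markers -1.39 without vehicle replicate 4. In an exact permutation test of library means, interferon response gave p = 0.057, adjusted p = 0.75. No gene passed limma's test (0 of 13711), and 470 had an unadjusted p under 0.05, 285 higher and 185 lower. The smallest p belonged to Nek3 (0.63), Igf2, insulin-like growth factor 2 (0.97), and Rapgef3 (0.70) on the higher side, and to Trex1, a cytosolic DNA exonuclease (-1.20), Capn5 (-0.67) and Fam217b (-0.65) on the lower side.

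**Figure D3:**
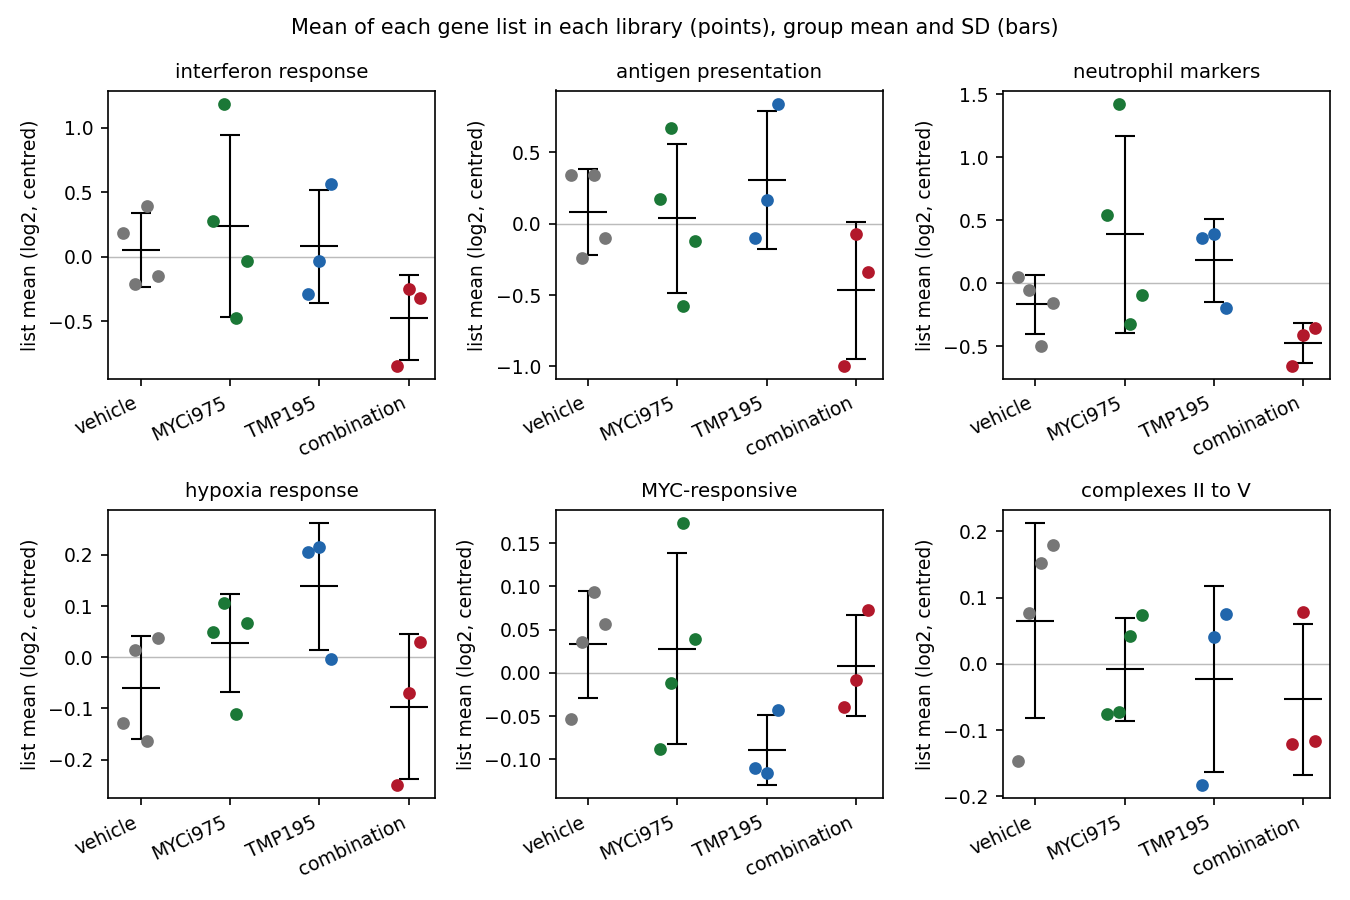
Mean of 6 gene lists in each library (points; log2, each gene centred on its mean over the 14 libraries) for vehicle (4), MYCi975 (4), TMP195 (3) and the combination (3), with group mean and SD (bars). The interferon response means of the combination libraries, -0.85, -0.32 and -0.25, lie below those of all vehicle libraries, and MYCi975 replicate 2 lies highest at 1.19.

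Against MYCi975 alone, neutrophil markers and interferon response genes ranked below other genes in the combination. These calls by camera did not hold with an estimated correlation (adjusted p = 0.86 for each). All 10 neutrophil markers were lower, by -0.86 on average (95% interval over libraries -1.67 to -0.05). Adjusted over the list alone, 7 of them passed limma's test, among them S100a9 (-1.14, adjusted p = 0.016), Trem1 (-1.06, adjusted p = 0.016) and Csf3r, the receptor of granulocyte colony-stimulating factor (-1.17, adjusted p = 0.042). Over all genes their adjusted p was 0.61. The count was 0 without combination replicate 1, 2 without combination replicate 2 or MYCi975 replicate 1 or 2, 3 without combination replicate 3 or TMP195 replicate 2, and 4 without vehicle replicate 4. Of the 12 endothelial markers Erg passed limma's test over its list alone (-0.64, adjusted p = 0.015), and 0 did without combination replicate 1 or 3. Members passed in 2 of 42 lists, with no adjustment over the lists. All 29 interferon response genes (mean -0.71) and all 20 antigen presentation genes (mean -0.51) were lower, and so was Ptprc by -0.81 (exact permutation p = 0.257). For both of these lists the 95% interval over libraries spanned both signs. With Ptprc as a covariate 1 of the 9 calls stayed, interferon response averaged -0.07, and antigen presentation (0.067), T cell (0.042) and macrophage markers (0.057) turned sign. Immediate early genes averaged -0.49, inflammatory cytokines -0.50, T cell markers -0.34, macrophage markers -0.32 and cytotoxic and NK cell markers -0.41, and cytosolic ribosomal protein genes averaged 0.14. Without MYCi975 replicate 2 the means were -0.52 for neutrophil markers, -0.39 for interferon response, -0.28 for immediate early genes and for inflammatory cytokines, -0.17 for T cell markers, -0.14 for macrophage markers, -0.27 for cytotoxic and NK cell markers and -0.29 for antigen presentation. Without combination replicate 1 antigen presentation averaged -0.24, and without combination replicate 2 cytosolic ribosome averaged -0.07, against 0.38 without combination replicate 3 and 0.29 without MYCi975 replicate 4.

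By camera, 9 of 42 lists were called for the combination against MYCi975, 1 higher and 8 lower, with adjusted p = 1.6e-12 for interferon response and 1.8e-07 for neutrophil markers. None held with an estimated correlation, where their adjusted p ran from 0.86 to 0.94. Calls ended without MYCi975 replicate 2 for T cell, macrophage and cytotoxic and NK cell markers and for cytosolic ribosome (-0.0019), the last also without MYCi975 replicate 1 (0.10) or combination replicate 2. The call of cytotoxic and NK cell markers also ended without MYCi975 replicate 1 (-0.32) or combination replicate 1 (-0.30) or 3 (-0.36), and that of macrophage markers without combination replicate 3 (-0.22). No gene passed limma's test over all genes (0 of 13711, smallest adjusted p = 0.61), and 1120 had an unadjusted p under 0.05, 430 higher and 690 lower. The smallest p belonged to Git1 (0.55), Nek3 (0.66) and Zfp169 (0.77), which were higher in the combination, and to Chil3, a chitinase-like protein of myeloid cells (-1.43), Isy1 (-0.96) and Sbno1 (-0.46), which were lower.

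Against TMP195 alone, antigen presentation, hypoxia response and glycolysis genes ranked below other genes in the combination and cell cycle genes above them. By camera, 13 of 42 lists were called, 2 higher and 11 lower, with adjusted p = 4e-16 for antigen presentation, 2.4e-06 for glycolysis and for hypoxia response and 1.7e-05 for cell cycle. None held with an estimated correlation, where their adjusted p ran from 0.51 to 0.69. All 20 antigen presentation genes were lower, by -0.77 on average, and 20 of 21 glycolysis genes, by -0.28 (95% interval over libraries -0.55 to -0.01). Hypoxia response genes averaged -0.24 (95% interval -0.44 to -0.03) and antioxidant response genes -0.26 (95% interval -0.47 to -0.04). Of 46 cell cycle genes 40 were higher (mean 0.15), as were 48 of 60 MYC-responsive genes (mean 0.10). For antigen presentation, cell cycle and MYC-responsive genes the 95% interval over libraries spanned both signs. Neutrophil markers averaged -0.66, interferon response -0.55, inflammatory cytokines -0.43, T cell markers -0.37, cytotoxic and NK cell markers -0.49, macrophage markers -0.28 and endoplasmic reticulum stress genes -0.13. Ptprc differed by -0.80 (exact permutation p = 0.1). With it as a covariate 5 of the 13 calls stayed, antigen presentation averaged -0.20, and interferon response (0.087), T cell (0.0096) and macrophage markers (0.10) turned sign. Without TMP195 replicate 3 antigen presentation averaged -0.50, interferon response -0.31, T cell markers -0.21, cytotoxic and NK cell markers -0.24 and macrophage markers -0.03. Without combination replicate 1 antigen presentation averaged -0.51 and interferon response -0.36, and without TMP195 replicate 1 macrophage markers averaged -0.44. Without combination replicate 2 endoplasmic reticulum stress genes averaged -0.06. Calls ended without TMP195 replicate 3 for macrophage and cytotoxic and NK cell markers, without combination replicate 2 for endoplasmic reticulum stress genes, and without combination replicate 3 for macrophage markers (-0.18) and MYC-responsive genes (0.07). With 3 against 3 libraries an exact permutation test of library means cannot go below 0.1. No gene passed limma's test (0 of 13711), and 603 had an unadjusted p under 0.05, 228 higher and 375 lower. The smallest p belonged to Pik3r3 (0.88), Errfi1 (0.57) and Igf2 (0.99) on the higher side, and to Tnfrsf9 (-0.81), Fabp5, a fatty acid carrier (-1.12), and Nfatc1 (-0.79) on the lower side.

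The interaction asks whether the effect of both compounds together differs from the sum of their single effects. Doses within the combination are not given in the sources used here. A change of dose therefore cannot be told apart from a departure from that sum. Neutrophil markers, interferon response, antigen presentation, hypoxia response and glycolysis genes ranked below that sum, and cell cycle and ribosomal genes above it. By camera, 17 of 42 lists were called, 5 higher and 12 lower. None held with an estimated correlation, where their adjusted p ran from 0.47 to 0.80. Neutrophil markers averaged -1.21 (95% interval over libraries -2.36 to -0.06), hypoxia response -0.32 (95% interval -0.60 to -0.05) and glycolysis -0.37 (95% interval -0.72 to -0.01). Cell cycle genes averaged 0.22 and cytosolic ribosomal protein genes 0.22, the latter 0.012 without combination replicate 2 and 0.46 without combination replicate 3. For interferon response, antigen presentation, cell cycle and cytosolic ribosome the 95% interval over libraries spanned both signs. With Ptprc as a covariate 6 of the 17 calls stayed, and interferon response (0.096), antigen presentation (0.018), T cell (0.13) and macrophage markers (0.16) and cytosolic ribosome (-0.11) turned sign, while neutrophil markers averaged -0.65. Adjusted over the list alone, 5 of 10 neutrophil markers, led by S100a9 (-1.56, adjusted p = 0.033), and Hdac5 (-0.65, adjusted p = 0.037) passed limma's test, in 2 of 42 lists, with no adjustment over the lists. The count of neutrophil markers was 0 without combination replicate 1 or 2, MYCi975 replicate 1, TMP195 replicate 1 or 2, or vehicle replicate 3, 2 without MYCi975 replicate 2 or vehicle replicate 2 or 4, 9 without MYCi975 replicate 3 and 10 without MYCi975 replicate 4. For the list of Hdac5 it was 0 without combination replicate 1 or 2, any of the MYCi975 libraries, TMP195 replicate 1, or vehicle replicate 2 or 4, and 2 without TMP195 replicate 3 or vehicle replicate 1. No gene passed limma's test over all genes (0 of 13711), and 656 had an unadjusted p under 0.05, 238 higher and 418 lower. The smallest p belonged to Zfp169 (1.10), Med24 (1.27) and Eml2 (1.24) on the higher side and to Nsun6 (-0.97), Narfl (-1.31) and Mreg (-0.95) on the lower side.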

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

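The tests of the 3 patterns weighed here were chosen after the values were seen, and so was the comparison of Xist, which replaced a correlation of Y-linked genes with Ptprc that was computed first and is not given because its values fall in separate clusters.

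With the preset correlation, camera called 17 of 42 lists for the interaction. None of these calls held with an estimated correlation (adjusted p from 0.47 to 0.80). Doses within the combination are not given in the sources used here. A departure from the sum of the single effects therefore cannot be told apart from a change of dose. Below the sum lay neutrophil markers (-1.21, adjusted p = 3.69e-09), interferon response (-0.74, adjusted p = 6.34e-09), antigen presentation (-0.73, adjusted p = 2.74e-08), inflammatory cytokines (-0.63, adjusted p = 2.27e-05), immediate early genes (-0.47, adjusted p = 0.00163), class IIa deacetylases and MEF2 factors (-0.39, adjusted p = 0.0108), glycolysis (-0.37, adjusted p = 0.000239), T cell markers (-0.36, adjusted p = 0.00328), the MYC network (-0.34, adjusted p = 0.0268), macrophage markers (-0.33, adjusted p = 0.0289), hypoxia response (-0.32, adjusted p = 9.8e-06) and endoplasmic reticulum stress genes (-0.21, adjusted p = 0.003). Above it lay cell cycle (0.22, adjusted p = 4.5e-06), cytosolic ribosome (0.22, adjusted p = 0.000186), cholesterol synthesis (0.16, adjusted p = 0.0296), MYC-responsive genes (0.10, adjusted p = 0.0276) and the mitochondrial ribosome (0.081, adjusted p = 0.0312). Without MYCi975 replicate 2 the means were -0.42 for interferon response, -0.41 for inflammatory cytokines, -0.26 for immediate early genes, -0.19 for T cell markers, -0.16 for macrophage markers, -0.22 for the MYC network, 0.08 for cytosolic ribosome and 0.05 for the mitochondrial ribosome, and the calls of the last 5 ended. Calls also ended without vehicle replicate 2 (mitochondrial ribosome, cytosolic ribosome, macrophage markers), 1 (cholesterol synthesis), 3 (mitochondrial ribosome, MYC-responsive genes) or 4 (macrophage markers), and without MYCi975 replicate 1 (mitochondrial ribosome, cholesterol synthesis, MYC-responsive genes) or 3 (cholesterol synthesis). They ended without TMP195 replicate 1 (mitochondrial ribosome, MYC-responsive genes), 2 (MYC-responsive genes, MYC network) or 3 (cholesterol synthesis, macrophage markers, MYC network, T cell markers), and without combination replicate 2 (mitochondrial ribosome, cytosolic ribosome, MYC network, immediate early genes, endoplasmic reticulum stress genes) or 3 (cholesterol synthesis, macrophage markers, MYC-responsive genes). Among the means that moved by over 1.5 times were cytosolic ribosome (0.012 without combination replicate 2, 0.46 without replicate 3), macrophage markers (-0.092 without TMP195 replicate 3), cholesterol synthesis (0.075 without combination replicate 3) and antigen presentation (-0.46 without TMP195 replicate 3 or combination replicate 1).

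The first pattern weighed is the lower interferon response and antigen presentation genes in the combination, whose joint mean was -0.54 from vehicle (95% interval -1.32 to 0.25), and -0.11 (-0.37 to 0.15), or 20.3% of that, with Ptprc as a covariate. It followed Ptprc over the 14 libraries (r = 0.97, rho = 0.96, permutation p = 1e-05 for each, the smallest they can give, adjusted p = 5e-05, 1 of 10 relations computed; r = 0.95 without the 2 libraries farthest from the median) and within groups (r = 0.96, rho = 0.95, permutation p = 1e-05). A candidate explanation is therefore a lower share of leukocytes in the combination libraries, with the difference of -0.11 left over, whether in the tumours or through an enrichment for tumour cells that was not equal in all groups, which was not tested. Not every leukocyte list went along, since mast cell and eosinophil markers differed by 0.21 (95% interval -0.18 to 0.59), B cell markers by -0.08 and dendritic cell markers by -0.07, none of them called. A lower complexity of the libraries cannot be told apart, since the lists' relation with the number of genes at the floor (r = 0.12, rho = 0.015, permutation p = 0.684 and 0.964; r = -0.18 without the 2 farthest) had a 95% interval of -0.44 to 0.61, although the combination libraries had fewer genes at the floor than vehicle and not more (by -180.6, exact permutation p = 0.771).

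The second pattern is the spread of the 13 mitochondrially encoded genes over the libraries. If mitochondrial content moved both kinds of genes alike, the nuclear respiratory chain genes would rise as much as the mitochondrially encoded list. Their slope on that list was 0.065 (95% interval -0.013 to 0.14). The relation had r = 0.46 and rho = 0.45 (permutation p = 0.0952 and 0.11), and r = 0.20 without the 2 farthest libraries. This argues against a content shared alike by both kinds of genes as the whole of the spread. A change in mitochondrially encoded RNA alone cannot be decided by this slope, since it need not move the nuclear genes. The list was higher where more genes lay at the floor (r = 0.65, rho = 0.63, permutation p = 0.0138 and 0.018, adjusted p = 0.0276 and 0.036; r = 0.61 without the 2 farthest; within groups r = 0.66, rho = 0.66), as would be seen where libraries with few distinct molecules hold a larger share of mitochondrial RNA, which is a candidate explanation. The relation cannot decide this, since a larger share of mitochondrial reads would by itself leave fewer reads for other genes. The depth of the libraries is unknown, so few reads cannot be told apart from few distinct molecules here. The mitochondrial ribosomal RNA gene mt-Rnr2 ran from 21.14 in combination replicate 3 to 23.09 in vehicle replicate 4, and its part was not tested. No biological explanation was tested beyond the content of mitochondria.

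The third pattern is that Y-linked genes were well above the floor in 5 libraries, namely vehicle replicates 1 and 3, MYCi975 replicate 2, TMP195 replicate 1 and combination replicate 1, where Eif2s3y ran from 6.586 to 8.002, while it was at the floor in the other 9. The labels give no sex of the hosts. Xist averaged 9.92 ± 0.38 (SD, n = 5) in these and 10.83 ± 0.51 (n = 9) in the others, a difference of -0.90 (exact permutation p = 0.00799), which is consistent with hosts of both sexes. Xist was still 9.515 or higher in each of the 5 libraries, so none of them was free of it, and what part the tumour line itself contributes was not tested. A loss of Y-linked genes to low library complexity would take other genes of that level along. Between the 5 and the other 9 libraries 3232 such genes had a median difference of 0.0045. Of these genes 95% lay between -0.32 and 0.36, which argues against such a loss. Of them 0 reached the difference of the Y-linked mean (1.91). The libraries were grouped by Eif2s3y, which is part of that mean, so its size follows in part from the grouping. Genes at the floor averaged 1672 ± 868 (SD, n = 5) in the 5 libraries and 1862 ± 539 (n = 9) in the others (exact permutation p = 0.613).

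Of 342 groups of 4 libraries examined, 15 (4.39%) held 1 library far from the others, where chance flags about 1 in 20 groups. In vehicle, replicate 4 stood apart for other histone deacetylases and sirtuins (list mean 0.069, others -0.03 to -0.02), Mvk (5.75, others 6.07 to 6.11), Tap2 (7.48, others 7.90 to 7.96) and Mreg (4.70, others 5.07 to 5.13), and replicate 1 for Errfi1 (9.92, others 10.04 to 10.05). In MYCi975, replicate 1 stood apart for extracellular matrix and mesenchymal genes (list mean 0.26, others -0.10 to -0.06), Eml2 (5.81, others 6.25 to 6.30) and Map3k6 (5.57, others 6.45 to 6.58), and replicate 2 for erythrocyte markers (list mean -1.48, others 0.38 to 0.44), Gadd45a (8.69, others 8.23 to 8.29) and Idh3a (8.43, others 8.59 to 8.60). Replicate 3 stood apart for Ndrg1 (10.06, others 10.47 to 10.54) and mt-Nd4l (11.37, others 12.55 to 12.60), and replicate 4 for Hspa1b (9.11, others 9.63 to 9.73) and Hdac9 (5.51, others 6.03 to 6.11).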

How the results depend on the processing

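The tests chosen after the data were seen were the exact permutation of library means, the count of lists called by fry, and the covariates Ptprc, mt-Rnr2 and Y-linked genes. No comparison had a gene past limma's threshold under any alternative or with any library left out (0 to 0), while 381 to 1120 genes had an unadjusted p under 0.05 with all libraries and the set choices. Over the alternatives and left-out libraries that count ran from 230 (TMP195 against vehicle without TMP195 replicate 2) to 1697 (the combination against MYCi975 without MYCi975 replicate 3). The number of lists called by camera was 0 with an estimated correlation and 0 by fry in all 6 comparisons, and 0 by exact permutation in the 5 comparisons it was run for. The smallest p of the exact permutation test is 0.1 for 3 against 3 libraries and 0.0286 for the others. After adjustment over 42 lists it could not pass in the former and hardly in the latter, so its 0 shows little. Without a filter on low values, 16 lists were called for the combination against MYCi975 in place of 9. With Ptprc as a covariate 4 were called in that comparison and 10 in place of 17 for the interaction. Leaving out each library in turn gave 5 (without MYCi975 replicate 1) to 14 (without MYCi975 replicate 3) lists for MYCi975 against vehicle, 11 to 17 for TMP195 against vehicle, 9 to 14 for the combination against vehicle, 7 to 12 against MYCi975, 12 to 16 against TMP195, and 12 to 20 for the interaction. A list's mean and median differed in sign in 6 lists each for MYCi975 and TMP195 against vehicle, 2 for the combination, and 1 and 2 for the combination against MYCi975 and TMP195, and its mean and camera in 2, 1 and 2 lists for TMP195 against vehicle and the combination against MYCi975 and TMP195, with 0 called lists among them. The other alternatives stayed within 1.5 times the number of lists, but a like number did not mean the same lists. With Ptprc as a covariate 5 of the 12 lists called for the combination against vehicle were still called, 5 of 13 against TMP195, 1 of 9 against MYCi975, 6 of 17 for the interaction, 8 of 10 for MYCi975 and 7 of 13 for TMP195 against vehicle.

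With Ptprc as a covariate the direction by camera reversed for interferon response with MYCi975 against vehicle (-0.0096), macrophage markers with the combination against vehicle (-0.0010), and against MYCi975 cytosolic ribosome (-0.11), antigen presentation (0.067), T cell (0.042), cytotoxic and NK cell (-0.0086) and macrophage markers (0.057). Against TMP195 it did so for interferon response (0.087), T cell (0.0096) and macrophage markers (0.10), and in the interaction for cytosolic ribosome (-0.11), interferon response (0.10), immediate early genes (0.029), T cell (0.13) and macrophage markers (0.16). With mt-Rnr2 as a covariate the mitochondrially encoded list reversed for the combination against vehicle (0.026), but mt-Rnr2 is itself transcribed from the mitochondrial genome, so this follows from the choice of covariate. Left-out libraries reversed interferon response with MYCi975 (-0.13 without MYCi975 replicate 2), the mitochondrially encoded list with TMP195 (0.42 without TMP195 replicate 1, -0.51 without replicate 3), antigen presentation with TMP195 (-0.048 without TMP195 replicate 3) and cytosolic ribosome for the combination against MYCi975 (-0.067 without combination replicate 2, 0.38 without replicate 3). Some lists called in 0 of these fits turned sign too. Examples are glycolysis with MYCi975 (0.089, and -0.015 without MYCi975 replicate 2) and MEF2-responsive genes with TMP195 (0.039, and -0.093 without TMP195 replicate 3). Ptprc marks leukocytes, so reversals of leukocyte lists with it as a covariate also follow in part from that choice. Beyond construction as a covariate or with fewer samples, the cause was not tested. The following counts cover only the lists called in the main fits and some further lists discussed. Over all alternatives, 2201 of their values stayed on their side of the threshold, 259 dropped below it, 35 passed it and 20 reversed. For genes 3991 values stayed. New calls of other lists are not in these counts. Without TMP195 replicate 2, for example, 17 lists were called for TMP195 against vehicle, and 11 of them were among the 13 of the main fit.

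Over all groups the replicate numbers showed no pairing of the libraries, since deviations of 19 pairs with 1 number correlated by 0.018 on average (-0.302 to 0.215), 6 pairs above 0.1. The 3 pairs of vehicle and TMP195 were among these 6 (0.107, 0.172 and 0.215), so a pairing there is not excluded, and the replicate block gave 9 lists in place of 13 for TMP195 against vehicle, 7 of them among the 13. Lists higher with TMP195 went from 7 to 3, and the calls that ended were complex I, complexes II to V, endoplasmic reticulum stress genes, antioxidant response, class IIa deacetylases and MEF2 factors and antigen presentation. The depth is unknown, so small differences of genes near the floor were not detectable here.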

Other observations

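The tests on splits of the libraries were set before the counts of unadjusted genes and of lists were seen, but those on genes past the adjusted threshold were chosen after a count of 0 was seen, which fixes their outcome.

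Chance could not be excluded for the lists called. Of the 35 splits of the vehicle and MYCi975 libraries 26 gave as many as the real 10 (highest other 20), for TMP195 12 of 35 (real 13, highest other 19), for the combination 15 of 35 (real 12, highest other 17), for the combination against MYCi975 25 of 35 (real 9, highest other 17), and for the interaction 7 of 100 drawn splits (real 17, highest other 21). For the combination against TMP195 3 of 10 did (real 13, highest other 14), and 10 splits are too few for a share under 0.05.

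Nor could it be excluded for genes at an unadjusted p under 0.05: 29 of 35 splits gave as many for MYCi975 (real 457, highest other 1953), 23 of 35 for TMP195 (real 381, highest other 1448), 17 of 35 for the combination (real 470, highest other 967), 7 of 35 for the combination against MYCi975 (real 1120, highest other 1917) and 37 of 100 for the interaction (real 656, highest other 2080). For the combination against TMP195 it was 4 of 10 (real 603, highest other 792), again too few splits. The highest other splits of the MYCi975 and vehicle libraries, of the TMP195 and vehicle libraries and of the interaction called several times the real number, which may come from a structure of the samples that was not tested. Of genes past limma's adjusted threshold the real count was 0 in each comparison, so all 35 splits of each 35, all 10 of 10 and all 100 of 100 gave as many, with highest other counts of 0 for MYCi975, 1 for TMP195, 1 for the combination, 2 and 1 for the combination against MYCi975 and TMP195, and 11 for the interaction.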
